A study of Mus musculus with 14 samples.

How the data were processed

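Satellite cells, the stem cells of skeletal muscle, were isolated from resting hind-limb, pectoral and triceps muscle of C57BL/6J mice and sequenced as 14 libraries of 1000 cells each. The gate was positive for integrin B1 and CXCR4 and negative for CD45, CD31, CD11b, Ter119 and Sca1. The first dataset has 4 libraries of FosGFP+ cells and 4 of FosGFP- cells from 4-month-old mice, and the series text gives 4 mice. The second has 3 libraries labelled FoscKO, with a conditional deletion of the transcription factor gene Fos, and 3 labelled Control, from 6-month-old mice, and the series text gives 3 mice. No label ties a library to a mouse. The series text gives a FosGFP+ gate for both arms of the second dataset, which may be a slip of the text and was left open.

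Per the labels' protocols, RNA was amplified with the SMART-Seq v4 kit, which does not keep the strand, tagged with Nextera XT and sequenced on an Illumina HiSeq instrument. The submitters' processing notes list STAR 2.5.0c, HTSeq 0.6.1, DESeq2 1.20.0, limma and the build GRCm38, with no role for any of them. The authors deposited 2 tables of raw counts per Ensembl gene, with 49671 genes each and 5 HTSeq lines that name no gene. As a check on the counting, genes lying wholly under an exon of a well-counted gene of the other strand had a mean count under 1 in 15 of 16 cases in the first table and in 21 of 23 in the second. The authors also deposited a table of their own comparison for each dataset, with log2 fold changes, their errors, p-values and adjusted p-values, in the column names that DESeq2 writes. Their fold changes are reference over test, opposite in sign to those given here (Spearman rho across genes of -0.997 and -0.991, where genes are not independent replicates), and were turned round wherever they are quoted. Their 14 further columns of per-library values carry names that match no label and were not used. Symbols, positions and exonic lengths came from GENCODE mouse release M21 (GRCm38), in which 49326 of the gene identifiers were found.

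The 2 datasets were fitted apart, since they were counted in separate tables. Genes were kept by filterByExpr of edgeR 4.0.16, scaled by TMM and tested by the quasi-likelihood F-test with robust dispersions, two-sided, with no covariate (R 4.3.3). Benjamini-Hochberg adjusted p-values under 0.05 were called. Levels are CPM, counts scaled to the TMM library size, with the SD over libraries. Fold changes are log2 values with their SE, in the direction FosGFP+ minus FosGFP- or FoscKO minus Control. The authors' p-values were read as deposited.

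The 25 gene lists were AP-1 subunits, other immediate early genes, heat shock and dissociation stress, cytokines and NF-kB targets, satellite cell identity, quiescence and Notch, myogenic commitment and fusion, cell cycle, NAD metabolism and ADP-ribosylation, growth factors and receptors, ribosome biogenesis, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes, interferon response, niche matrix, apoptosis and p53 targets, and markers of mature fibre, endothelium, blood leukocyte, erythroid cell, fibro-adipogenic progenitor, smooth muscle and pericyte, Schwann cell and tenocyte. Each list was tested by camera (limma 3.58.1) with a preset correlation of 0.01, with an estimated correlation beside it, and by fry, over lists with at least 5 tested members. The genes called in the first dataset were tested as 2 sets, without Fos, in the fit of the second. Overlaps, chosen after values were seen, were tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 12 overlaps, and against 10000 random lists drawn in 20 bins of expression.

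Lists, tests, thresholds and the rule for named genes were fixed before the data were examined. The rule takes Fos, the 12 largest rises and falls among called genes with non-overlapping libraries and a mean of at least 5 CPM (or, where fewer than 5 pass, the 5 smallest p), up to 4 members of each list and the 5 smallest adjusted p per direction in the authors' tables. The genes in the text are a part of those, chosen after their values were seen, and a gene outside the rule is named as such.

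Alternatives fixed with them were DESeq2 size factors, no filter, a filter at 5 CPM, limma-voom, DESeq2 1.42.0, the replicate number as a block, library sizes without the 20 most abundant genes, and each library left out. Scaling by total counts, TMM from genes of at least 50 CPM, counts less an even background, and limma-voom with quality weights were chosen after seeing the data, as was the use of an estimated correlation and of fry in settings other than TMM with all libraries. That background is the reads per exonic kb over 1464 olfactory, vomeronasal and taste receptor genes, times each gene's exonic length. Changes were simulated in genes of at least 5 CPM, with genes drawn independently. On simulated counts for the first comparison, 175 of 200 genes changed 4-fold and 61 of 200 changed 2-fold were called, with 12 of 19229 unchanged genes. For the second, 149 of 200 and 37 of 200 were called, with 10 of 20250 unchanged genes. Library measures were compared by exact permutation tests, two-sided.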

Results

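RNA of freshly sorted mouse satellite cells was sequenced in 14 libraries: 4 labelled FosGFP+ and 4 labelled FosGFP-, sorted by a GFP reporter of Fos, 3 labelled FoscKO and 3 labelled Control. Counts in genes per library ran from 3806776 to 5983711 in FosGFP+, from 2652230 to 4067543 in FosGFP-, from 4797954 to 10241655 in FoscKO and from 5326686 to 6930696 in Control. The share of reads that fell in genes was 19.7% ± 2.62 (SD, n = 4) in FosGFP+ and 12.9% ± 1.74 (SD, n = 4) in FosGFP- (exact permutation p = 0.0286, the smallest this design allows). It was 22.9% ± 7.16 (SD, n = 3) in FoscKO and 18.2% ± 1.15 (SD, n = 3) in Control (exact permutation p = 0.4, where the smallest possible is 0.1). Reads spread evenly over the genome, estimated from receptor genes of smell and taste, made up 8.77% ± 1.78 of gene counts in FosGFP+ and 15.6% ± 2.77 in FosGFP- (SD, n = 4; exact permutation p = 0.0286). In FoscKO they made up 7.44% ± 3.93 and in Control 9.68% ± 0.828 (SD, n = 3). Replicates 1, 2 and 3 of FoscKO had 30.2%, 15.9% and 22.7% of their reads in genes. Replicate 1 had a count in 31483 genes, fewer than replicates 2 and 3, at 36054 and 36804.

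**Figure D1:**
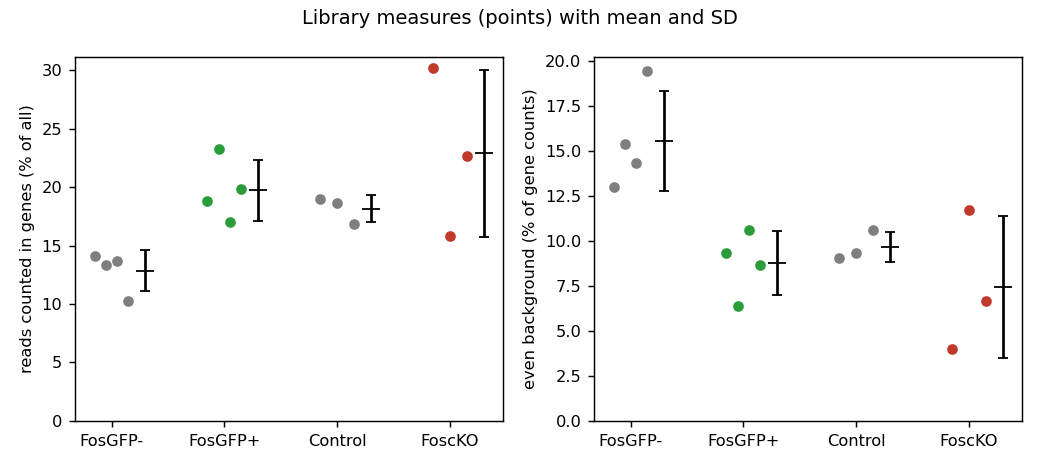
Each point is a library; the left panel plots reads counted in genes as a percent of all reads, the right panel the estimated even background as a percent of gene counts, with the mean and SD of each group. The 4 FosGFP+ libraries lie above the 4 FosGFP- libraries on the left and below them on the right, and FoscKO replicate 1 is at 30.2% on the left.

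The first comparison asks how satellite cells sorted as positive for the Fos reporter differ from those sorted as negative. In the libraries labelled FosGFP+, 26 of 29 genes that make ribosomes were higher, and of 25 genes of cytokine and NF-kB signalling 14 were higher and 1 lower. Camera with an estimated correlation gave the ribosome list an adjusted p of 0.0645 and the cytokine list an adjusted p of 0.17, neither past the threshold, while both passed with the preset correlation. With an estimated correlation neither passed with DESeq2 size factors (0.135 and 0.23) or without the most abundant genes (0.0758 and 0.152), both planned settings. Both lists passed it with total counts (0.0149 and 0.0438) and with TMM from well-expressed genes (0.0127 and 0.0453), settings chosen after seeing the data. After the even background was subtracted, the ribosome list passed it (0.0254) and the cytokine list did not (0.292). Also higher were Hmox1, Srxn1 and Txnrd1, which counter oxidative stress, the transcription factor genes Fosl1 and Myc, and the myogenic regulator Myod1. Hmox1, which degrades heme, stood at 3004 ± 986 CPM against 326 ± 97.8 (SD, n = 4 each), a log2 fold change of 3.21 ± 0.28 (SE). Myod1 stood at 1799 ± 140 CPM against 470 ± 157 (SD, n = 4), a log2 fold change of 1.94 ± 0.21 (SE). The Notch target Hes1 fell from 200 ± 64.3 to 18.9 ± 7.6 CPM (SD, n = 4), and Apod, which encodes a lipid-binding secreted protein, fell from 57.8 ± 16.3 to 4.15 ± 1.83 CPM. Fos mRNA itself was lower, not higher, in the libraries labelled FosGFP+, at 4586 ± 1050 against 10921 ± 2123 CPM (SD, n = 4), a log2 fold change of -1.25 ± 0.21 (SE) with an edgeR adjusted p of 9.33e-04. None of the 4 FosGFP+ libraries, at 3098 to 5398 CPM, reached the lowest FosGFP- library, at 7908. Every direction below is therefore one between labels, and the reporter's own mRNA was not analysed here.

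In GRCm38, Fos (ENSMUSG00000021250) lies on chromosome 12 from 85473890 to 85477273, Fosl1 (ENSMUSG00000024912) on chromosome 19 from 5447547 to 5455946, Myod1 (ENSMUSG00000009471) on chromosome 7 from 46376474 to 46379099, and Hmox1 (ENSMUSG00000005413) on chromosome 8 from 75093621 to 75100589. Hes1 (ENSMUSG00000022528) and Apod (ENSMUSG00000022548) lie on chromosome 16, from 30064384 to 30067796 and from 31296192 to 31314808.

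Of 20698 genes tested, 2125 were higher and 383 lower in the libraries labelled FosGFP+ by edgeR, where 5457 had an unadjusted p under 0.05 and 1035 would by chance. The libraries of the groups did not overlap for 19.3% of genes, against 2.86% by chance. The authors' deposited table lists 2917 genes higher and 505 lower in FosGFP+. The balance of directions depended on the scaling: with total counts 1005 genes were higher and 2243 lower, and with TMM from well-expressed genes 722 and 5252. Those scalings shifted the log2 fold changes of all genes by a median of -0.40 and -0.58, and subtraction of the background by -0.18. The scalings were run for Fos, which stayed lower, and for 54 other named genes, of which 0 changed direction. Further genes named for this comparison, such as Cspg4 and Emp1, were not among the 54. The calls of Mcm7, Pcna, Uqcrfs1 and Pygm were lost with total counts and with TMM from well-expressed genes. Those of Pcna (0.64; edgeR adjusted p = 0.0551), Mki67 (-2.44; 0.119) and Pygm were lost after the subtraction.

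Among the largest rises were Neu2, which encodes a sialidase, at a log2 fold change of 3.62 ± 0.32 (SE), Vasn at 2.81 ± 0.45 and Tnfrsf19, a receptor of the TNF family, at 2.35 ± 0.27. The redox enzymes Srxn1 and Txnrd1 rose by 2.65 ± 0.21 and 2.23 ± 0.24. Slc22a4, a transporter of ergothioneine, rose by 2.51 ± 0.30 and the chromatin protein gene Hmga1 by 2.31 ± 0.33. The edgeR adjusted p of these 7 genes lay between 2.13e-05 and 7.78e-04. Each was higher in 4 of 4 libraries, which the rule for the largest rises required. In the authors' deposited table Asb5 was among the smallest adjusted p-values, at 1.24e-22, with a log2 fold change of 2.15 ± 0.20 (SE) in FosGFP+. On the other side, Hoxa10 fell by 2.52 ± 0.35 (SE), the glucocorticoid target Tsc22d3 by 1.91 ± 0.31 and the stress-induced mTOR inhibitor gene Ddit4 by 2.01 ± 0.36, with edgeR adjusted p-values of 2.91e-04, 8.16e-04 and 0.0017. The 12 largest falls also held the olfactory receptor genes Olfr1277, at -2.25 (edgeR adjusted p = 0.0193), and Olfr49, at -2.08 (0.0424). Genes of that class served to estimate the background, which was larger in FosGFP-.

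**Figure D2:**
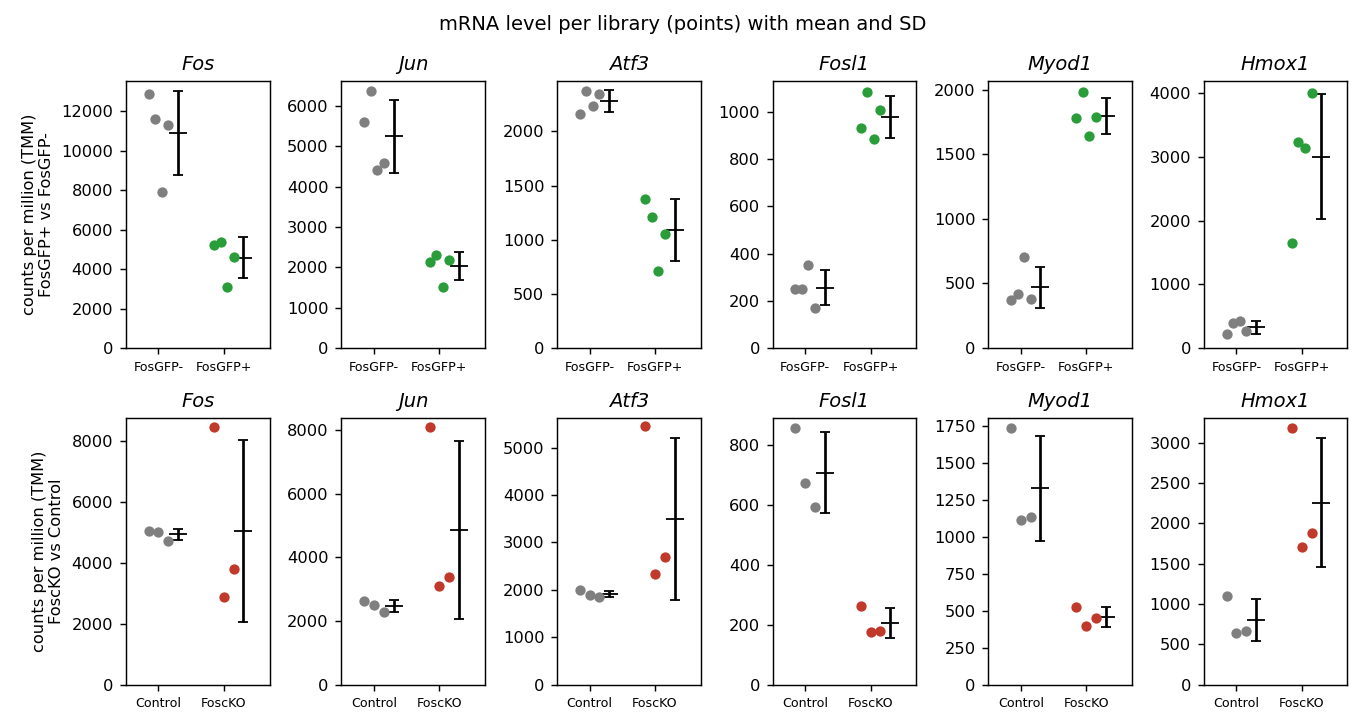
Each point is the level of a gene in a library, in TMM-scaled CPM on a linear axis from 0, for FosGFP- and FosGFP+ (upper panels) and Control and FoscKO (lower panels), with the mean and SD beside the points. Fos, Jun and Atf3 are lower and Fosl1, Myod1 and Hmox1 higher in the 4 FosGFP+ libraries, while Fosl1 and Myod1 are lower in the 3 FoscKO libraries than in each Control library.

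Of 12 AP-1 subunit genes tested, 3 were higher and 4 lower in FosGFP+, with 5 higher and 4 lower when adjusted over the list alone. Fosl1 rose by 1.93 ± 0.21 (SE; edgeR adjusted p = 1.14e-04), while Jun fell by 1.37 ± 0.19 and Atf3 by 1.07 ± 0.20. Of 42 other immediate early genes, 13 were higher and 7 lower, or 16 and 9 adjusted over the list alone. Myc rose by 1.64 ± 0.19, Ier5 by 1.90 ± 0.20 and Ccn2 by 1.46 ± 0.17, whereas Ccn1 fell by 1.41 ± 0.19. Heat shock and dissociation stress genes went both ways, with 4 higher and 4 lower of 22, and 4 and 5 adjusted over the list alone. Hmox1 and the endoplasmic reticulum chaperone gene Hspa5, which rose by 1.67 ± 0.20, were among the former. The inducible chaperone genes Hspa1a and Hspa1b, which fell by 1.91 ± 0.26 and 1.63 ± 0.26, were among the latter. With total counts 8 other immediate early genes were higher and 14 lower, and 4 and 8 heat shock genes. With TMM from well-expressed genes the numbers were 8 and 16, and 2 and 12. Subtraction of the background gave 9 and 10, and 2 and 6. AP-1 genes numbered 2 higher and 4 lower in each of these settings.

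Ribosome biogenesis genes rose in 26 of 29 cases, also 26 when adjusted over the list alone, with a median log2 fold change of 1.2. Examples are the small nucleolar particle protein gene Nhp2, at 149 ± 3.85 against 43.2 ± 7.05 CPM (SD, n = 4), the nucleolin gene Ncl, at 1015 ± 90.5 against 414 ± 33.7, and Rrs1, at 168 ± 24.5 against 52.8 ± 10.8. The camera adjusted p was 8.78e-30 with the preset correlation and the adjusted p = 0.0645 with an estimated correlation. Of 25 cytokine and NF-kB target genes, 14 rose and 1 fell, or 16 and 2 adjusted over the list alone, with a median of 1.00 and a camera adjusted p of 8.07e-11 (adjusted p = 0.17 with an estimated correlation). Csf1, which encodes a macrophage growth factor, rose by 2.13 ± 0.29 (SE), the chemokine gene Cxcl5 by 2.64 ± 0.44, Cd44 by 1.69 ± 0.20 and Nfkb2 by 1.60 ± 0.23. These medians stayed above 0 under each scaling. The members called higher numbered 20 and 15 for ribosome biogenesis with total counts and with TMM from well-expressed genes. For cytokine and NF-kB genes they were 12 and 10, with 2 lower in each.

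Growth factor and receptor genes rose in 13 of 35 cases and fell in 1, or 15 and 1 adjusted over the list alone (camera adjusted p = 0.00112; adjusted p = 0.353 with an estimated correlation), as with the oncostatin M receptor gene Osmr, by 1.7 ± 0.24 (SE), and Vegfa, by 1.40 ± 0.23. Glycolysis genes rose in 6 of 20 cases, or 9 adjusted over the list alone (camera adjusted p = 4.08e-05; adjusted p = 0.279 with an estimated correlation), among them the hexokinase gene Hk2, by 1.92 ± 0.23, and the glucose transporter gene Slc2a1, by 1.46 ± 0.18. Satellite cell identity genes rose in 9 of 22 cases, also 9 over the list alone (camera adjusted p = 2.98e-04; adjusted p = 0.413 with an estimated correlation), including Des by 1.09 ± 0.17 and Vcam1 by 1.2 ± 0.20. Apoptosis and p53 target genes rose in 9 of 20, or 10 with 1 fall over the list alone (camera adjusted p = 1.38e-04; adjusted p = 0.279 with an estimated correlation), including Mdm2 by 1.19 ± 0.21. Matrix genes of the niche rose in 6 of 28, with 6 rises and 1 fall over the list alone (camera adjusted p = 0.00701; adjusted p = 0.58 with an estimated correlation), including Plaur by 1.65 ± 0.23. Oxidative phosphorylation genes rose in 6 of 51, also 6 over the list alone (camera adjusted p = 0.00112; adjusted p = 0.433 with an estimated correlation), including Uqcrfs1 by 0.85 ± 0.17, whose call was lost with total counts and with TMM from well-expressed genes. For other immediate early genes camera gave an adjusted p of 0.0161 (adjusted p = 0.75 with an estimated correlation). With TMM the medians of these 7 lists ran from 0.32 to 0.53, while all 4002 genes of at least 50 CPM had a median of 0.57. Of all 20698 genes tested, 2125 were called higher. The lists were not matched on expression, so these rises need not be particular to them. The medians of the 7 lists were below 0 with TMM from well-expressed genes. Member calls turned too. With total counts 6 growth factor, 5 glycolysis, 6 identity, 7 apoptosis, 3 matrix and 0 oxidative phosphorylation genes were called higher, and 5, 0, 5, 3, 2 and 2 lower. With TMM from well-expressed genes 6, 4, 6, 7, 2 and 0 were called higher and 8, 3, 7, 6, 7 and 10 lower. After the subtraction 6, 5, 8, 7, 3 and 1 were called higher and 2, 0, 1, 0, 0 and 0 lower. The camera calls of immediate early and oxidative phosphorylation genes were lost there, with total counts and after the background was subtracted, that of niche matrix genes with the first and the last of these (0.0655 and 0.179), and that of satellite cell identity with the last (0.0637).

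Quiescence and Notch genes were higher in 3 and lower in 3 of 28 cases, or 4 and 6 adjusted over the list alone. The median was -0.23, and camera called the list lower with total counts (adjusted p = 0.0443), with TMM from well-expressed genes (0.0114) and after the subtraction (0.019), but not with TMM (0.299). With an estimated correlation the adjusted p was 0.557, 0.349, 0.465 and 0.814 in these settings, so that no call was left. Gas1 fell by 1.25 ± 0.26 (SE) beside Hes1, and the signalling inhibitor gene Spry2 rose by 1.5 ± 0.25. Of 19 genes of myogenic commitment and fusion, 4 rose and 2 fell, or 4 and 3 over the list alone, with Myod1 and the cell cycle inhibitor gene Cdkn1a, which rose by 1.04 ± 0.18, among the rises. Of 36 cell cycle genes 2 rose and 3 fell, or 4 and 5 over the list alone. Mcm7 rose by 0.80 ± 0.19 and Pcna by 0.81 ± 0.20, and Ccnd3 fell by 1.03 ± 0.21. Mki67, at -1.11 ± 0.33, kept its call without FosGFP- replicate 2 but lost it without each of the other libraries, at -1.21 to -0.89. NAD metabolism and ADP-ribosylation genes rose in 3 of 30 cases and fell in 1, the same numbers over the list alone, with Nampt, the enzyme of NAD salvage, up by 1.17 ± 0.19. Of 21 interferon response genes 4 rose, also 4 over the list alone, including Ifitm3 by 1.26 ± 0.20, and of 9 mitochondrially encoded genes 0 passed. The median of the latter, 0.17, turned to -0.23 with total counts, to -0.43 with TMM from well-expressed genes and to -0.07 after the subtraction. With total counts 1 quiescence, 2 commitment, 0 cell cycle, 3 NAD, 1 interferon and 0 mitochondrially encoded genes were called higher, and 9, 5, 7, 5, 2 and 2 lower. With TMM from well-expressed genes 1, 2, 0, 1, 1 and 0 were called higher and 15, 10, 16, 11, 4 and 3 lower. After the subtraction 1, 4, 1, 3, 1 and 0 were called higher and 6, 3, 1, 0, 0 and 0 lower. Camera gave adjusted p-values from 0.109 to 0.852 for the lists of AP-1, heat shock, quiescence, commitment, cell cycle, NAD, interferon and mitochondrial genes and for the 7 lists of cell type markers other than endothelium. Medians and camera directions differed in sign for heat shock and interferon genes, each with a median of -0.05.

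Endothelial markers were the list that camera called lower, with an adjusted p of 0.0114 (adjusted p = 0.406 with an estimated correlation) and 13 of 14 members below 0. Ramp2, at 16.9 ± 5.79 against 42.2 ± 10 CPM (SD, n = 4), was the 1 member that passed, also 1 adjusted over the list alone. Fibro-adipogenic markers had 1 fall among 19, Smoc2, at -3.84 ± 0.78 (SE). Its call was lost without FosGFP+ replicate 2 (-3.77) or 4 (-3.67), with no filter (-3.76) and with limma-voom without (-3.23) or with quality weights (-3.17). Pericyte markers had 1 rise, Steap4, and 1 fall, Cspg4, among 12. The numbers were the same for both lists over the list alone. Of 26 mature fibre markers 1 rose, Pygm, by 0.67 ± 0.20 (SE). That call was lost with the replicate block (0.657; edgeR adjusted p = 0.0607) and with total counts. It was also lost without FosGFP+ replicate 1 or 4 or FosGFP- replicate 2, 3 or 4 (0.58 to 0.72), and 0 passed over the list alone. No marker of leukocytes (14), erythroid cells (5), Schwann cells (11) or tenocytes (9) passed. With TMM from well-expressed genes, markers called lower numbered 10 of endothelium, 5 of fibre, 5 of fibro-adipogenic progenitors, 3 of pericytes, 3 of leukocytes, 2 of Schwann cells, 2 of tenocytes and 0 of erythroid cells. With total counts they numbered 4, 3, 3, 2, 1, 2, 1 and 0. After the subtraction they numbered 1, 0, 1, 0, 0, 0, 0 and 0.

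By fry, which tests whether the genes of a list move on balance in 1 direction and compares them with no other genes, 9 lists passed. Ribosome biogenesis, cytokine, glycolysis, oxidative phosphorylation, apoptosis, growth factor and satellite cell identity genes were higher, and endothelial markers and cell cycle genes lower, with adjusted p-values from 3.98e-04 to 0.0351. Of the lists that camera called, other immediate early genes (0.202) and niche matrix genes (0.154) did not pass fry, and cell cycle genes (0.0351) passed fry but not camera. For change in either direction, fry gave adjusted p-values from 0.0764 to 0.538 for fibre, leukocyte, erythroid, Schwann cell and tenocyte markers and mitochondrially encoded genes, and at most 0.0162 for every other list. With total counts fry called ribosome, cytokine, glycolysis and apoptosis genes higher, but not growth factor (0.333), satellite cell identity (0.353) or oxidative phosphorylation genes (0.17). With TMM from well-expressed genes it called ribosome (0.00178) and cytokine genes (0.0269) higher, and oxidative phosphorylation (0.0168) and other immediate early genes (0.00321) lower. After the subtraction it called ribosome, cytokine, glycolysis and apoptosis genes higher, and endothelial markers lower. Cell cycle genes stayed lower by fry with total counts and with TMM from well-expressed genes (0.00801 and 0.00301), but not after the subtraction (0.0603) or with DESeq2 size factors. With total counts and with TMM from well-expressed genes fry also called endothelial, quiescence (0.00801 and 0.00301), commitment, NAD, erythroid, fibro-adipogenic, pericyte and Schwann cell lists lower, and with the latter AP-1, heat shock, interferon, leukocyte and tenocyte lists as well. Camera with an estimated correlation called ribosome, cytokine, growth factor, glycolysis and apoptosis genes higher with total counts (adjusted p = 0.0149 to 0.0438) and with TMM from well-expressed genes (0.0127 to 0.0481). After the subtraction it called ribosome biogenesis genes alone (0.0254). It called no list with DESeq2 size factors or without the most abundant genes, where its smallest adjusted p was 0.135 and 0.0758.

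The second comparison asks what changes in satellite cells when Fos is deleted. In the libraries labelled FoscKO, Emp1, a membrane protein gene, stood at 393 ± 55.5 CPM against 1668 ± 233 in Control (SD, n = 3 each), Asb5 at 225 ± 36.5 against 775 ± 109, Fosl1 at 206 ± 49.2 against 706 ± 135 and Myod1 at 459 ± 66 against 1329 ± 355. Spry1, an inhibitor of growth factor signalling, stood at 1637 ± 704 against 371 ± 28.7 CPM, Steap4, a metal reductase gene, at 329 ± 65.9 against 77.6 ± 27.1, and the chemokine gene Ccl2 at 1075 ± 515 against 243 ± 87.5. For each of these genes the 3 FoscKO libraries lay on 1 side of the 3 Control libraries. The genes were named for small p-values in these same libraries, so that is no further support. The groups did not overlap for 12.2% of all genes, against 10% by chance. Fos mRNA was not lower in the libraries labelled FoscKO, at 5041 ± 2982 against 4934 ± 174 CPM (SD, n = 3), a log2 fold change of 0.03 ± 0.39 (SE; edgeR adjusted p = 0.996). The 3 FoscKO libraries held 8442, 2876 and 3805 CPM of Fos, and without replicate 1, the first of these, the log2 fold change was -0.56 with an edgeR adjusted p of 0.707. Which part of Fos the conditional allele removes is not in the labels, so a count over the whole gene need not show a deletion.

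By edgeR, 0 of 21885 genes were called (smallest adjusted p = 0.0801), with 779 higher and 429 lower at an unadjusted p under 0.05, where 1094 in all would be by chance. DESeq2 called 59 genes higher and 32 lower, limma-voom 4 and 6, and edgeR without FoscKO replicate 1 called 16 and 27. The authors' deposited table lists 42 genes higher and 27 lower in FoscKO. In the authors' deposited table the smallest adjusted p-values were those of Emp1 (6.80e-08), Spry1, Steap4 and Asb5 (3.61e-06 each), Ccl2 (1.01e-04), Chrnd (2.92e-04), Nab2 (3.23e-04), Fosl1 and Slc22a4 (4.27e-04 each) and Hmga1 (8.75e-04). The log2 fold changes in the authors' deposited table were -1.81 for Emp1, -1.56 for Asb5, -1.47 for Fosl1, -1.60 for Slc22a4 and -1.73 for Hmga1, and 1.90 for Spry1, 1.85 for Steap4, 1.83 for Ccl2, 1.81 for Chrnd and 1.7 for Nab2. The libraries of the groups did not overlap for 12.2% of genes, against 10% by chance. Total counts and TMM from well-expressed genes each shifted the log2 fold changes of all genes by a median of -0.18.

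In GRCm38, Emp1 (ENSMUSG00000030208) lies on chromosome 6 from 135362545 to 135383173 and Asb5 (ENSMUSG00000031519) on chromosome 8 from 54529580 to 54587842. Spry1 (ENSMUSG00000037211) lies on chromosome 3 from 37639947 to 37644598 and Steap4 (ENSMUSG00000012428) on chromosome 5 from 7960457 to 7982213.

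No member of any list was called over all genes in this comparison, so the counts here are those adjusted over the list alone. Camera called 13 lists with the preset correlation and 0 with an estimated one. By fry 0 passed, with a smallest adjusted p of 0.195 for movement on balance in 1 direction, that of interferon response genes, and of 0.185 for change in either direction. Under the other scalings 0 lists passed either, with a smallest adjusted p of 0.105 by camera with an estimated correlation and of 0.136 by fry, and without FoscKO replicate 1 the former also called 0. Mature fibre markers were lower in 6 of 27 cases and 25 of 27 lay below 0, with a median log2 fold change of -0.86 (camera adjusted p = 5.49e-13; adjusted p = 0.297 with an estimated correlation). Myh4, at 30.4 ± 5.31 against 76.5 ± 11.6 CPM (SD, n = 3), Mylpf, at 14.6 ± 4.77 against 56.1 ± 33.3, and Ckm, at 169 ± 88.4 against 393 ± 92.8, encode proteins of fast fibres or their energy supply. Other immediate early genes were higher in 14 of 42, with a median of 0.62 (camera adjusted p = 3.00e-12; adjusted p = 0.568 with an estimated correlation), among them Egr3, at 49.1 ± 20.8 against 11.9 ± 4.12 CPM, and Btg2, at 5112 ± 1994 against 1925 ± 19.5. Of 22 heat shock and stress genes 1 was higher, Hmox1, and 21 lay above 0 (camera adjusted p = 9.54e-11; adjusted p = 0.568 with an estimated correlation). Cytokine and NF-kB genes were higher in 5 of 26 cases, including Lif at 97.6 ± 34.1 against 24.8 ± 9.83 CPM and Cxcl10 at 191 ± 48.2 against 62.6 ± 14.5, and lower in 1, Cd44, at 192 ± 26.4 against 371 ± 41.2 (camera adjusted p = 3.08e-09; adjusted p = 0.568 with an estimated correlation). Quiescence and Notch genes were higher in 4 of 27, including Spry1 and the Notch target Heyl, at 1136 ± 544 against 427 ± 44.2 CPM (camera adjusted p = 5.34e-07; adjusted p = 0.568 with an estimated correlation).

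Of 21 interferon response genes 1 was higher, Gbp2, at 110 ± 42.2 against 33.9 ± 9.65 CPM (camera adjusted p = 2.27e-04; adjusted p = 0.297 with an estimated correlation). Of 20 genes of commitment and fusion 1 was lower, Myod1, while 15 lay above 0 (camera adjusted p = 0.00201; adjusted p = 0.568 with an estimated correlation). The camera calls and medians of these 7 lists kept their direction under each scaling and without FoscKO replicate 1, but most medians depended on that library. Without it the median fell from 0.62 to 0.2 for other immediate early genes (camera adjusted p = 0.0107), from 0.54 to 0.26 for heat shock genes (2.88e-05) and from 0.61 to 0.25 for cytokine and NF-kB genes (0.00229). It fell from 0.31 to 0.18 for quiescence (1.23e-04), from 0.47 to 0.29 for interferon (0.00126) and from 0.48 to 0.31 for commitment genes (0.0483), and from 0.17 to 0.11 for pericyte markers (0.0463). That of fibre markers was -0.97 (3.52e-19). With an estimated correlation the adjusted p without that library was 0.362 for interferon and fibre lists and 0.868 or 0.872 for the others. With total counts the first 6 medians were 0.33, 0.3, 0.35, 0.08, 0.28 and 0.2. Camera also called oxidative phosphorylation (3.33e-05, 0 of 51 members), satellite cell identity (0.00152, 0 of 22), niche matrix (0.0166, 0 of 28) and apoptosis genes (0.0225, 0 of 21) higher, each with an adjusted p = 0.711 with an estimated correlation. Their medians were 0.26, 0.37, 0.22 and 0.28, while all 3869 genes of at least 50 CPM had a median of 0.245. The lists were not matched on expression. Camera called endothelial markers lower (adjusted p = 0.016, 0 of 16 members) and pericyte markers higher (adjusted p = 0.031, 1 of 14, Steap4), both with an adjusted p = 0.568 with an estimated correlation. The calls of niche matrix, apoptosis and endothelial genes were lost with total counts, that of satellite cell identity after the background was subtracted (0.0799), and the pericyte median turned to -0.08 with total counts. Without FoscKO replicate 1 the calls of satellite cell identity (0.569), oxidative phosphorylation (0.325), niche matrix (0.475), apoptosis (0.969) and endothelium (0.287) were lost. Ribosome biogenesis genes, with a median of -0.14 over 30 and 0 members past, had a camera adjusted p of 0.0853 (adjusted p = 0.711 with an estimated correlation). It was 9.09e-06 with total counts (adjusted p = 0.346 with an estimated correlation) and, with a median of -0.35, 1.09e-05 without FoscKO replicate 1. Without that library camera with the preset correlation also called cell cycle genes higher (0.0107) and glycolysis genes lower (0.006). With an estimated correlation the adjusted p was 0.868 for each of these 3 lists without it. AP-1 subunits had 1 member higher, Jdp2, and 1 lower, Fosl1, of 13, with a camera adjusted p of 0.075. In cell cycle (36), NAD metabolism (32), growth factor (34), glycolysis (20) and mitochondrially encoded genes (9), and in markers of leukocytes (13), fibro-adipogenic progenitors (19), Schwann cells (11) and tenocytes (9), 0 members passed and camera adjusted p-values ran from 0.0725 to 0.839. Medians and camera directions or means differed in sign for NAD metabolism, with a median of 0.11 and a mean of -0.06, for mitochondrially encoded genes, with a median of -0.04 and a mean of 0.01, and for erythroid markers, with 0.1 and -0.03. The 4 erythroid markers measured were too few to test as a list.

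**Figure D3:**
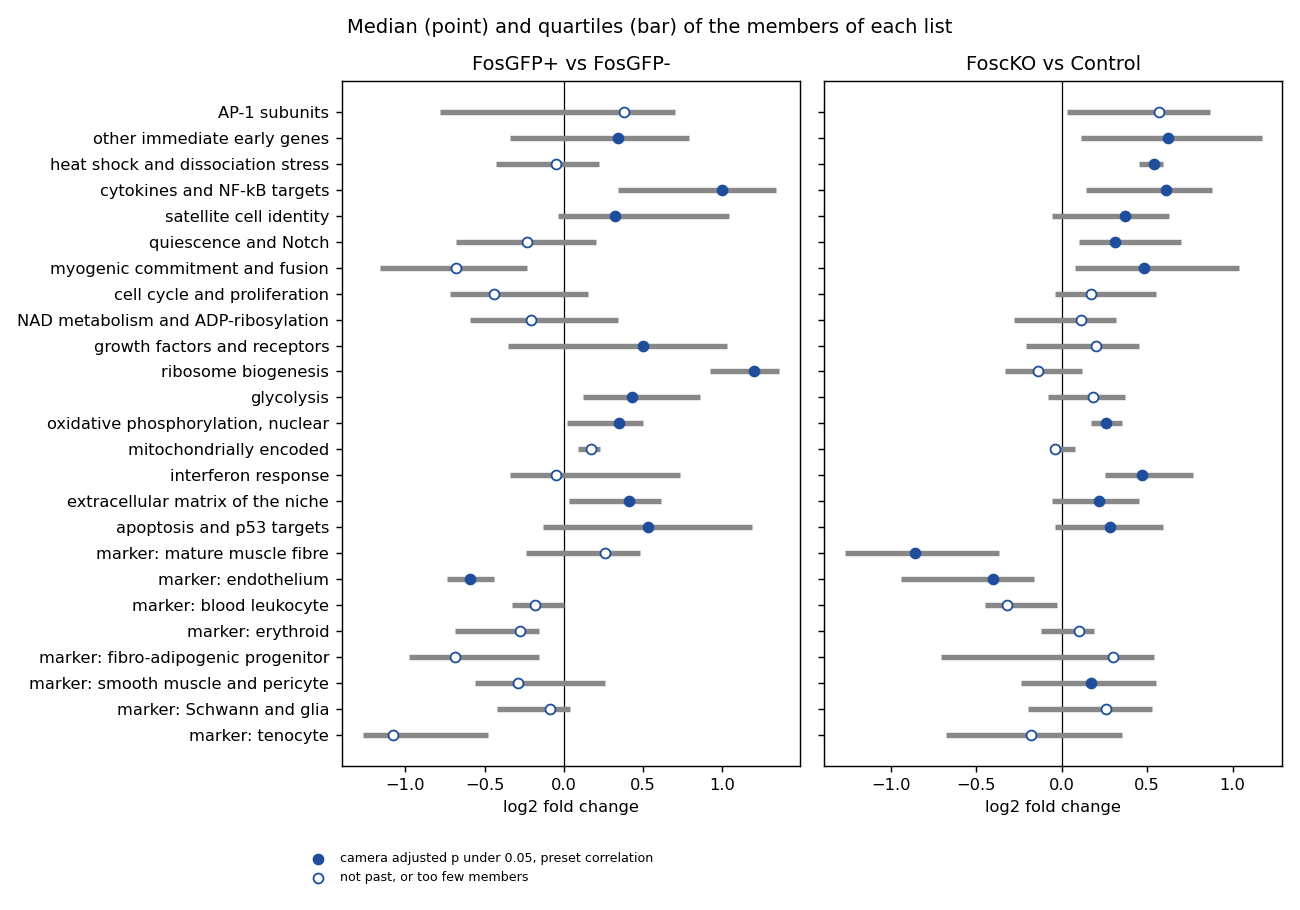
Each point is the median log2 fold change of the tested members of a list, and the bar runs between the quartiles, for FosGFP+ minus FosGFP- (left) and FoscKO minus Control (right); filled points passed camera with the preset correlation. Ribosome biogenesis has the highest median on the left, at 1.2, and mature fibre markers the lowest on the right, at -0.86; no list passed with an estimated correlation in these fits, with TMM.

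The third comparison asks whether the genes that differ with the reporter also differ when Fos is deleted. Since edgeR called 0 genes in FoscKO, the overlaps rest on the calls of DESeq2 or of the authors, and were chosen after their values were seen. Of the 32 genes that DESeq2 called lower in FoscKO, 24 were higher and 0 lower in the libraries labelled FosGFP+ by edgeR, where 5.95 would be by chance (Fisher's exact p = 5.92e-12, 7.11e-11 adjusted over the 12 overlaps tested). Those 24 include Fosl1, Myod1, Emp1, Asb5, the interleukin 1 receptor gene Il1r1, Hmga1, Slc22a4 and Neu2. Asb5, for example, stood at 1573 ± 328 CPM in FosGFP+ and 361 ± 24 in FosGFP- (SD, n = 4). Emp1 stood at 2120 ± 292 and 578 ± 178. Random lists of the same expression shared a median of 12, so 5.95 is too low a chance level, and 0 of 10000 shared as many as 24. Fisher's test and the random lists treat genes as independent. The genes higher in FosGFP+ had an estimated correlation of 0.468 in the FoscKO fit, so the Fisher p-values here can be too small. Over libraries, 1 of 10 splits, the real one, shared as many, which is the smallest share possible. Each of the other splits mixes FoscKO with Control, which by itself lowers the number of calls that could be shared. With total counts or with TMM from well-expressed genes, 22 of the 32 were still called higher in FosGFP+. Of the 59 genes that DESeq2 called higher in FoscKO, 15 were higher in FosGFP+, among them Hmox1, Steap4 and Ccl2, against 11 by chance (Fisher's exact p = 0.18, adjusted 0.24) and a median of 21 in random lists. Another 5 were lower, among them Gas1 and Btg2 (1.21 by chance; Fisher's exact p = 0.00705, adjusted 0.0169). The share that was higher in FosGFP+ differed between the genes lower and the genes higher in FoscKO (Fisher's exact p = 6.63e-06). By the calls of the authors' deposited tables, of 26 genes lower in FoscKO and tested in both, 19 were higher in FosGFP+, against 3.81 by chance (Fisher's exact p = 3.21e-11, adjusted 1.93e-10). Of 41 genes higher in FoscKO in the authors' deposited tables, 14 were higher in FosGFP+ as well, against 6.02 by chance (Fisher's exact p = 0.00146, adjusted 0.00439). The numbers by chance for the authors' calls are over 19820 genes, those for the DESeq2 calls above over 11274. With DESeq2 calls in both datasets, over 11266 genes, 19 of 58 were shared against 14 by chance (Fisher's exact p = 0.127, adjusted 0.19). The excess among genes higher in both may therefore come from the wider set of genes. Without FoscKO replicate 1, edgeR called 26 tested genes lower in FoscKO, and 21 of them were higher in FosGFP+.

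For the genes called in the first comparison as whole sets, the direction in the second depended on the scaling and on FoscKO replicate 1. The 2124 genes higher in FosGFP+ had a median log2 fold change of 0.16 in FoscKO, with 31.2% of them below 0 against 53.3% of the other genes, and a camera p of 6.98e-05 with the preset correlation (p = 0.583 with an estimated correlation). The other genes were not matched on expression. All 3869 genes of at least 50 CPM in that fit had a median of 0.245, so these shares do not set the 2124 apart from well-expressed genes. The median of the genes higher in FosGFP+ was -0.035 without FoscKO replicate 1, with an unadjusted camera p of 0.0113, and -0.13 with total counts in both fits, with one of 0.00749. It was -0.148 with TMM from well-expressed genes, with a camera p of 7.09e-05, and -0.066 for the 200 genes of smallest p, with one of 0.00242. With the stricter filter it was 0.078, with a camera p of 0.229. With an estimated correlation none of these settings gave a call (p = 0.67 without FoscKO replicate 1, 0.244 with total counts, 0.178 with TMM from well-expressed genes, 0.661 for the 200 genes and 0.838 with the stricter filter). The 371 genes lower in FosGFP+ had a median of 0.01 (camera p = 0.278; p = 0.525 with an estimated correlation). In some other settings that set passed camera, with an estimated correlation too, at a median above 0. Its median was 0.117 with the replicate block in the first fit and 0.166 after the subtraction. It was 0.173 without FosGFP- replicate 3, and 0.093 for the 196 tested among the 200 genes of smallest p. Elsewhere the set did not pass with an estimated correlation, and these calls are not adjusted over settings.

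**Figure D4:**
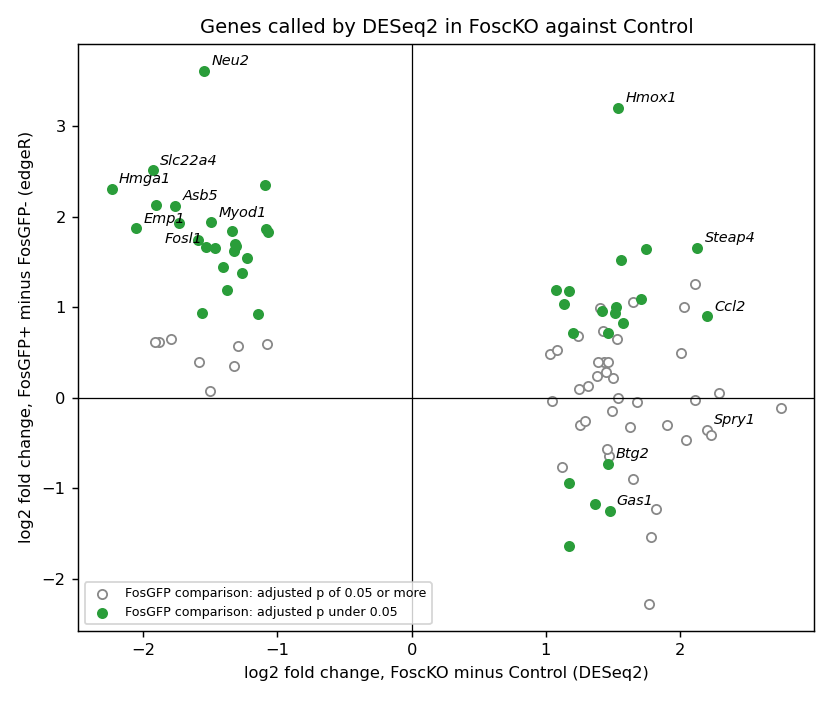
Each point is 1 of the 91 genes that DESeq2 called in FoscKO against Control, with its log2 fold change there on the horizontal axis and its log2 fold change in FosGFP+ minus FosGFP- by edgeR on the vertical axis; filled points passed an edgeR adjusted p of 0.05 in the latter. All 32 genes on the left lie above 0, and 24 of them are filled.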

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

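Among 120 sets of 4 libraries in the first dataset, a library stood far from its group in 4, where chance gives about 6, or 1 in 20. Replicate 3 of FosGFP- held 703 CPM of Myod1, against 375 to 422 in the other libraries of that group. Replicate 1 of FosGFP+ held 47.2 CPM of Tsc22d3, against 123 to 128 in the others. The same library held 1237 CPM of Vcam1, against 2092 to 2228 in the others. Replicate 3 of FosGFP+ held 8.25 CPM of Ramp2, against 19.3 to 20.5 in the others.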

How the results depend on the processing

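Total counts, TMM from well-expressed genes, subtraction of the background and limma-voom with quality weights were chosen after seeing the data; the other settings were planned. For FosGFP+ against FosGFP-, called genes ran from 2280 with the replicate block to 3423 with DESeq2 among the settings fixed beforehand, and from 1893 to 2566 without single replicates, but 5974 with TMM from well-expressed genes and 1579 after the subtraction, which tested 15692 genes. Fos stayed lower and called in each setting, at -1.36 to -1.06 without single replicates, and 10 to 11 lists passed there. Of 810 planned values of 54 other named genes 791 kept direction and call, 19 lost the call (Mki67, Smoc2, Pygm and Steap4) and 0 reversed; of 216 added ones 13 lost it. For FoscKO against Control, called genes numbered 0 with DESeq2 size factors and without the abundant genes, 131 without a filter, 30 with the stricter filter, 10 with limma-voom, 91 with DESeq2, 0 to 43 without single replicates, 45 with total counts, 43 with TMM from well-expressed genes, 15 after the subtraction and 215 with quality weights. The replicate block gave 43 genes and a Fos value of -0.13. Deviations of libraries with the same number correlated by -0.02 to 0.02 in the first dataset and by -0.01 to 0.13 in the second. Those with different numbers ran from -0.153 to 0.153 over both datasets. The data thus show no pairing by number but cannot exclude it, since spread between libraries could hide it. Fos, at 0.03 and uncalled, changed sign with the stricter filter (-0.079), limma-voom (-0.129), total counts (-0.283), TMM from well-expressed genes (-0.267), the subtraction (-0.145) and quality weights (-0.352), and ran from -0.561 to 0.333 without single replicates; its adjusted p was 0.301 or above in each. Of 465 planned values of 36 named genes there 345 kept their side, 120 came to pass and 0 reversed. The median in FoscKO of genes higher in FosGFP+ lost its call with the stricter filter (0.078), with changes over 1 (0.089) and after the subtraction (0.018). It was negative with the 200 smallest p (-0.066), total counts (-0.13) and TMM from well-expressed genes (-0.148), and ran from -0.035 to 0.319 without single replicates, the lowest without FoscKO replicate 1. The median of genes lower in FosGFP+ was negative with DESeq2 size factors (-0.007), no filter (-0.043), the stricter filter (-0.095), limma-voom (-0.172), changes over 1 (-0.068), total counts (-0.229) and TMM from well-expressed genes (-0.232), and ran from -0.161 to 0.305 without single replicates. That median was positive with the replicate block in both fits (0.063) or in the first alone (0.117). It was also positive after the subtraction (0.166), with quality weights (0.058) and with the 200 smallest p (0.093). Of these settings, all but quality weights passed camera with the preset correlation. With an estimated correlation the call with the block in both fits was lost. Among fits without single replicates, only that without FosGFP- replicate 3 (0.173) passed with an estimated correlation. The cause of these changes was not tested, beyond the smaller numbers of genes or libraries that some settings use. In counts simulated at the depth, spread and number of libraries of the data, 2-fold changes were called for 61 of 200 genes in the first comparison, 6 of 100 below and 55 of 100 at or above the median level of 21.4 CPM. They were called for 37 of 200 in the second, 4 of 100 below and 33 of 100 at or above 22 CPM. The changed genes were drawn from those of at least 5 CPM, and all genes were simulated independently. All simulated calls numbered 260 and 202, against 2508 and 0 in the data, so these rates need not hold for the real fits. What depth, the number of libraries and dispersion each contribute was not separated.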

Other observations

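The tests of background, exchanged labels, time since induction, scaling, Art1 and the splits for genes shared with the FosGFP+ rises were chosen after the results were seen, and those of fibre RNA, of a single library and of the remaining splits before. Each hypothesis here was found and tested on the same libraries.

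Immediate early genes split within the first comparison. The 11 that fell in FosGFP+ were Arc, Atf3, Btg2, Ccn1, Fos, Gadd45g, Jun, Junb, Nr4a1, Socs3 and Zfp36, and the 16 that rose include Fosl1, Myc, Ier5, Klf4, Klf6, Dusp5, Dusp6 and Plk2; these were named after their values were seen, and all are members of the fixed lists. Nr4a1 stood at 659 ± 128 CPM against 1851 ± 627 (SD, n = 4), and Junb at 3098 ± 245 against 5000 ± 308. An even background is argued against as the whole cause, since after its subtraction all 11 stayed lower and called. The test is a weak one: the subtraction, with TMM applied again, also moved the log2 fold changes of all genes by a median of -0.185. That favours calls of a fall, and genes far above the background could hardly change. An exchange of the group labels cannot be told apart from correct labels: 24 of the 32 genes lower in FoscKO were higher in FosGFP+, but Fos mRNA does not show that the labels of that comparison are right. A candidate explanation is a longer time since induction in FosGFP+ cells, with the stable reporter outlasting Fos mRNA; of 14 rapidly induced genes outside AP-1, picked after values were seen, 9 were below 0, 5 of them called, while Klf4 was called higher, which leaves it open.

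More genes rose than fell in the libraries labelled FosGFP+, which also had the larger share of reads in genes. With total counts the share of calls that were higher was 30.9%, against 84.7% with TMM, so the balance may come from where the scaling puts its centre. The share was 83.7% after the background was subtracted. That does not test the background, which stays open, because the counts were scaled by TMM again after the subtraction and the share follows that centre. A larger amount of RNA per cell in FosGFP+ stays open and was not tested, since the libraries hold no added standard.

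Of 27 fibre markers 25 lay below 0 in FoscKO, but edgeR called none over all genes, and the list passed camera with the preset correlation (adjusted p = 5.49e-13), not with an estimated one (adjusted p = 0.297), and not fry (adjusted p = 0.614). FoscKO replicate 1 was not the source: without it the median was -0.97. Less fibre RNA among the sorted cells is a candidate explanation; the gate selects cells that carry integrin B1 and CXCR4, and whether it removes fibre fragments was not tested, and 24 of the 27 markers lay within 2 SE of the median; Actn3, Mylpf and Ttn did not, and 1 marker, Eno3, is also in another list. Among the most abundant markers Acta1 stood at 659 ± 411 CPM against 1071 ± 377 in Control (SD, n = 3), Atp2a1 at 234 ± 77.6 against 399 ± 197 and Actn3 at 245 ± 85.8 against 232 ± 73.3. Art1, a muscle ADP-ribosyltransferase gene, was not called by edgeR either (adjusted p = 0.386). It was called in the authors' deposited table (log2 fold change of -1.62, adjusted p = 0.0257 there). Art1 stood at 1.12 ± 0.93 against 7.45 ± 0.91 CPM (SD, n = 3) and lay 2.64 SE from the fibre median. That is too near to set it apart from the fibre markers and too far to place it among them. This rests on the second comparison alone, since Art1 was not among the genes tested in the first. An effect of the genotype on Art1 and the fibre markers stays open, untested.

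Other splits of the 8 libraries of the first dataset numbered 35 with the real one, and 1 of 35, the real one, gave as many as 2508 called genes. The highest of the others gave 0, but each of those mixes the 2 groups, which by itself lowers the count. Chance is therefore unlikely for that count, at the smallest share that 35 splits allow, but is not excluded. The splits also take the libraries as exchangeable, while no label ties them to mice. For the lists, 7 of 35 splits gave at least the real 10 with the preset correlation, the highest of the others 14, so chance is not excluded for the number of lists. The 6 libraries of the second dataset have 10 splits, too few for a share under 0.05. There the real split and the highest other gave 0 and 0 called genes (10 of 10 splits as large), 13 and 18 lists (3 of 10), a set median of 0.164 and 0.35 in size (7 of 10), and 24 and 2 genes shared with the FosGFP+ rises by DESeq2 (1 of 10). The other splits mix the groups here too, which by itself lowers the number of shared genes.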
